A study of Mus musculus with 131 samples.

How the data were processed

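The series holds 131 mouse samples of strain C57BL/6J from work in which embryonic stem cells (ESCs) were injected into diploid host embryos. Of these, 6 are amplicon samples of the Gjb2 35delG site in tissues at P42, 40 are single GFP cells and 55 single RFP cells of E4.0 blastocysts, and 3 are bisulfite libraries of cultured cells: mouse embryonic fibroblasts (MEF) at p2, Gjb2-35delG ESCs at p7 and Actin-RFP ESCs at p10. An E7.5 embryo sample, 9 RFPpos cells, 8 GFPpos cells and 9 RFPpos-GFPpos cells were not analysed here. Sequencing was paired-end with 150 bp reads per the labels. Groups were taken from the labels, and the choice of comparisons, gene lists, thresholds and alternatives was made before the data were examined, except where stated otherwise.

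Single cells were picked with a micromanipulator and their full-length cDNA was amplified with a kit that adds no molecular identifiers, per the labels' protocols. The submitters' processing notes name fastp 0.20.0, STAR 2.7.3a, featureCounts 2.0.0, StringTie 2.0, deepTools 3.3.1, DESeq2 1.30.0 and the build mm10, with no role or order. The deposited expression values are a signal, gene read counts divided by one factor per cell by the authors. They are whole multiples of one step per cell, and dividing by that step gave whole reads for 100% of the values within 0.01. The filter that left 13927 genes is not given in the sources used here, and 13922 of the Ensembl IDs were matched to a symbol while 5 were not. The deposited log2 fold change of the authors was used only for a correlation across genes, because how cells entered their model is not given in the sources used here.

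All 95 cells passed a minimum of 2000 detected genes. No label names an embryo, so each group of cells was treated as 1 sample and no test was run between groups, which is also why no count model was fitted to the recovered reads. Reads were summed over the cells of a group and scaled to CPM, the usual unit relative to all reads of the group, with an exact 95% Poisson interval. The log2 ratio of RFP over GFP cells was taken on CPM + 1, a pseudocount that understates the change of low genes. The median log2 ratio of each fixed list was placed as a percentile among 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression. Shares of cells were given with exact 95% binomial intervals. Both kinds of interval cover counting error only, since PCR copies and cells of the same embryo are not independent.

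Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on log2(CPM + 1) of 2000 variable genes, 20 principal components, 10 neighbours and resolution 1, with scaled values limited to 10. Clusters were called epiblast-like (EPI-like), primitive-endoderm-like (PrE-like) or trophectoderm-like (TE-like) from fixed marker lists. Each cell was a picked cell in its own tube, so no doublet caller was run, and pairs of cells picked together cannot be excluded. Genes detected per cell were also compared after each cell was thinned to 500000 reads. Named genes had a read in at least 50% of the cells of a group and at least 10 CPM in a group, with predicted genes left out. Of the 5061 genes that met this, the 12 with the highest and the 12 with the lowest log2 ratio were named, besides members of the lists. The lists covered lineage markers, feeder fibroblasts, oocyte genes, core, naive and formative pluripotency, genes of the totipotent-like state, DNA methylation, p53 and apoptosis, inhibitors of apoptosis, Myc and the nucleolus, glycolysis, respiration, the cell cycle, stress, immediate early genes, FGF, Hippo, Wnt and Nodal signalling, adhesion, connexins, imprinting, X inactivation, placenta and ribosomal proteins.

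In the amplicon work, the target site was amplified from tissue DNA and barcoded products were pooled, per the labels' protocols. The deposited table gives counts of reads that the authors classed as 35delG, wild type (WT) or Other, and how reads were classed is not given in the sources used here. The table has 65 amplicons named by a number or 35G and a tissue. No name is the title of a sample, so no amplicon was assigned to a sample or a group. Shares of reads carry 95% Wilson intervals, which cover counting error only.

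Bisulfite libraries were made by ligation of adapters to converted single-stranded DNA, per the labels and design text, and the aligner and caller are not given in the sources used here. The authors deposited, for each window of 200 bp, the methylation fraction averaged over its CpGs and the counts of methylated and unmethylated calls. Chromosome lengths are those of GRCm38, the assembly behind mm10. Each covered window has at least 5 calls per CpG, so a minimum of 5 calls removed none. Means were taken over the 7638465 windows with a value in all 3 libraries. Each library is the only one of its kind, so differences are between libraries and were not tested.

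The planned promoter window was 1000 bp upstream to 500 bp downstream of the transcription start. The annotation used, RefSeq genes of GRCm38.p6, gives gene ends without strand. The end with more CpGs in its window was used instead, and it had at least 2 times the CpGs of the other end in 60.5% of 20229 genes. These windows are called gene ends here, and some lie at the 3′ end of a gene. Gene ends that were named by size of difference or drawn for random lists needed at least 3 windows with a value in every library; fixed list members needed 1, and Gata6 among the developmental genes had 2. The 10 gene ends with the largest and the 10 with the smallest difference from MEF for each ESC library, and 6 and 6 between the ESC libraries, were named, besides members of the lists. These held maternally methylated imprinted regions (gDMRs), paternally methylated imprinted genes, germline, pluripotency, fibroblast, trophectoderm, developmental and housekeeping genes. Differences of a list from MEF were placed among 10000 random lists matched to its members in 20 bins of MEF level, since a high start leaves more to lose. Intervals on gene ends are 95% Wilson intervals on calls.

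The steps were tested on simulated data. For RFP against GFP cells, 200 of 13927 simulated genes were changed by 4-fold. Their median log2 ratio was 1.93 where raised and -1.92 where lowered, and 100% had the right sign. Of 200 lists of unchanged genes in that simulation, 7.5% fell outside the middle 95% of random lists. For the promoter lists, simulated over 13627618 windows, a list set to 5% was recovered at 5% and no unchanged list moved by more than 0.459 points. The simulated libraries shared the same base level in each window apart from small random noise. The 0.459 points reflect the noise chosen and set no limit for real libraries. The 5% was set in and read from the same windows, so its recovery was fixed in advance and checks the computation only. It does not show whether the gene end used is the promoter. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

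Alternatives changed one choice at a time: cell filter, average over cells, pseudocount, normalization, low genes, variable genes, resolution and clusters for the cells; the denominator for the amplicons; windows, call minimum and weighting for methylation; and window length, list mean and gene end for the promoter lists. Chosen after the data were seen were the leaving out of cells above 10% mitochondrially encoded reads, clusters without the lineage marker genes, the gene end with fewer CpGs, the matching of random promoter lists on the MEF level and the restriction to members with at least 2 times the CpGs at the richer end.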

Results

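The data covered reconstructed mouse embryos and the ESC lines used to make them. Single cells of E4.0 blastocysts carried an Actin-GFP or an Actin-RFP transgene, 40 and 55 cells respectively. In the design text, Actin-RFP ESCs were injected into Actin-GFP eight-cell embryos, so RFP marks the injected line and GFP the host. The GFP cells held 223.6 M reads in total, 2.0 to 8.32 M per cell with a median of 5.61 M. The RFP cells held 311.3 M reads, 0.518 to 9.56 M per cell with a median of 5.58 M. Read totals of the 65 Gjb2 amplicons ran from 287851 to 727021, with a median of 453740. The bisulfite libraries held 317 M calls for MEF, 288 M for Gjb2-35delG ESCs and 319 M for Actin-RFP ESCs.

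The amplicons addressed how far tissues of the mice carried the Gjb2 35delG allele, a single-base deletion in a gap junction gene whose loss causes deafness. Gjb2 lies on chromosome 14, from 57098602 to 57104702 in GRCm38. In the amplicons named 35G, 35delG reads made up 99.6% in brain (Wilson interval 99.57% to 99.61%, 499639 reads), 99.7% in heart, 98.1% in liver (98.04% to 98.12%), 99.4% in testis and 99.8% in tail. WT reads made up 0.232% in brain, 0.121% in heart, 1.77% in liver, 0.403% in testis and 0.0153% in tail. The liver share of WT reads lay above the intervals of the other 4 tissues, but each tissue was a single amplicon, so no spread between animals was available. Other reads stayed between 0.150% and 0.201% of these 5 amplicons.

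The remaining 60 amplicons carried a number from 1 to 12 in place of 35G, and no label says which animals these were. Numbers 5 to 11 lay between 94.3% and 99.8% 35delG in all 5 tissues of each. Numbers 1 to 4 and 12 lay at 0.0185% to 0.601%. No amplicon fell from 1% to 90%. The lowest 35delG share among the 35 rich numbered amplicons was in brain of number 6, where WT reads reached 5.53% (5.46% to 5.60%).

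**Figure D1:**
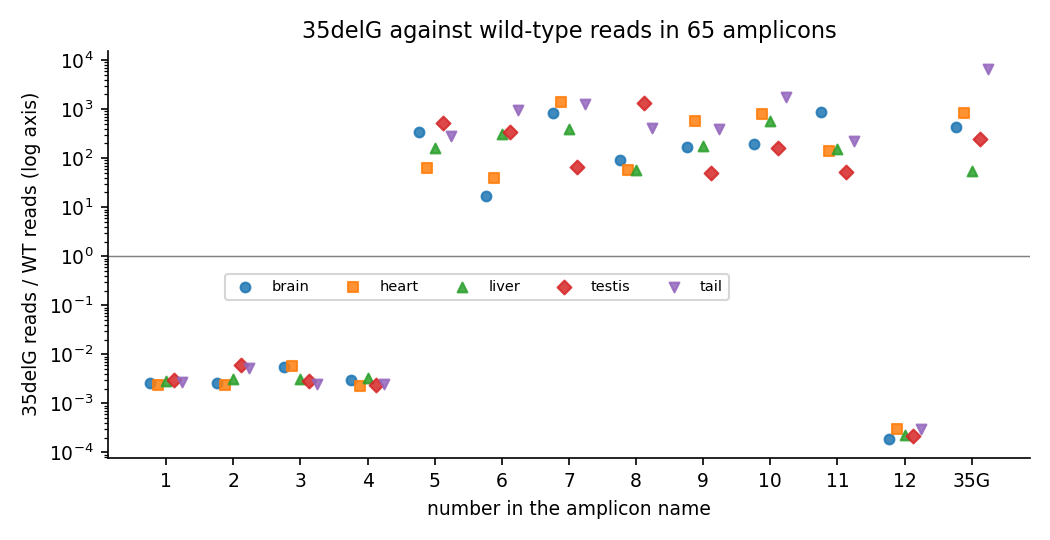
Ratio of 35delG to WT reads (log axis) in each of 65 amplicons, by the number in the amplicon name (horizontal axis), with tissues as symbols. Numbers 5 to 11 and 35G lie above the line at 1 in every tissue, and numbers 1 to 4 and 12 below it.

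The single cells addressed which lineage the injected and the host cells had entered by the blastocyst stage. Of the 40 GFP cells, 39 (exact interval 86.8% to 99.9%) lay in TE-like clusters, and of the 55 RFP cells, 52 (94.5%, 84.9% to 98.9%) lay in EPI-like clusters. The trophectoderm contributes to the placenta, and the epiblast forms the embryo proper. The exceptions were 1 EPI-like GFP cell and 3 RFP cells in TE-like clusters (5.45%, 1.14% to 15.1%). The markers did not clearly bear out the name for these 3, whose mean log2 levels were 4.92 (EPI) and 3.24 (TE) in cell 44, 1.51 for both in cell 14 and 1.19 and 1.47 in cell 6. The EPI-like GFP cell, cell 27, was at 1.79 (EPI) and 0.936 (TE), and its EPI level was below the 2.72 of GFP cell 1, which was TE-like. By marker z-scores without clusters, 1 RFP cell was TE-like and 48 were EPI-like, while 36 GFP cells were TE-like and none was EPI-like. The z-scores put 4 GFP and 6 RFP cells in PrE-like. A z-score is relative to all cells, so the PrE list can rank first in a cell at a low level. No RFP cell had a mean log2 PrE level above 1.39 (cell 55), against 6.71 in GFP cell 36. All 4 exceptions by cluster had over 10% mitochondrially encoded reads. With the 5 cells above that limit left out, the shares by cluster were 39 of 39 and 51 of 51. No cluster was PrE-like. Clusters made without the marker genes gave the same shares, but they were named from the same markers, so the names were not checked independently. How cells were chosen for picking is not stated, so the shares describe the picked cells. Nearly all GFP cells were TE-like and nearly all RFP cells EPI-like. The ratios of RFP over GFP cells below therefore cannot tell the injected or host origin of the cells from their lineage.

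Trophectoderm markers were lower in RFP cells, with 13 of 14 measured members at least 1 lower on the log2 scale and a list median of -4.47 (percentile 0 among random lists). Krt8 and Krt18, keratins of the trophectoderm epithelium, stood at 2505 and 4220 CPM in GFP cells against 51.6 and 106 CPM in RFP cells. Gata3, a transcription factor of the trophectoderm, was at 795 against 7.37 CPM, and Cdx2, which specifies that lineage, at 29.8 against 0.0321 CPM. Epiblast markers were higher in RFP cells, with 9 of 12 at least 1 higher, none at least 1 lower and a median of 4.20 (percentile 100). Tdgf1, a co-receptor of Nodal, reached 1388 CPM in RFP cells against 2.32 CPM in GFP cells, and Fgf4, the epiblast ligand that instructs the primitive endoderm, 516 against 3.57 CPM. Nanog (26.8 CPM in GFP, 19.1 CPM in RFP) and Zfp42 (387 and 355 CPM) were near each other. Nanog has pseudogenes, and how reads shared with them were counted is not given in the sources used here.

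Primitive endoderm markers were also lower in RFP cells, at a median of -2.42 (percentile 0), with 11 of 12 at least 1 lower. Gata6, which drives this lineage, was at 111.5 CPM in GFP cells and 2.90 CPM in RFP cells, and Dab2, an endocytic adaptor, at 371 and 10.8 CPM. The other 10 measured members were at 10 CPM or more in at most 9 GFP cells, and Pdgfra (5.45 CPM) and Gata4 (4.30 CPM) in 2. When each cell weighed the same on the log scale the list median was -0.32. GFP cells 36 and 39 had mean log2 marker levels of 6.71 and 5.0, beside trophectoderm levels of 6.63 and 4.99.

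**Figure D2:**
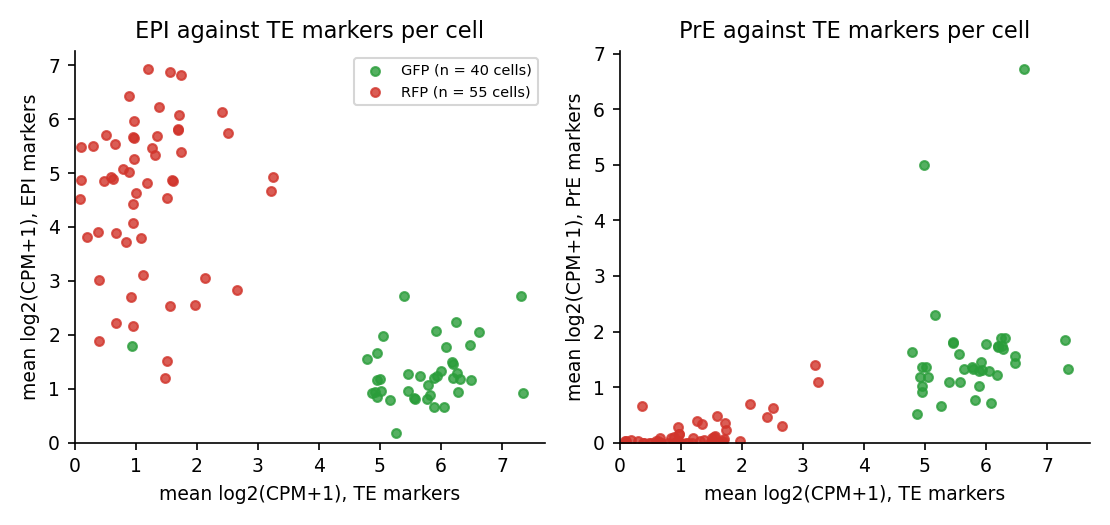
Mean log2(CPM + 1) of the EPI markers (left) and the PrE markers (right) against that of the TE markers, 1 point per cell, for 40 GFP and 55 RFP cells. All but 1 of the GFP cells lie to the right of the RFP cells on the TE axis.

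Among the 12 genes with the lowest ratio, Adh1, an alcohol dehydrogenase that oxidises retinol, was at 1832 CPM in GFP cells (Poisson interval 1826 to 1837) and 2.20 CPM in RFP cells (2.04 to 2.38), a log2 ratio of -9.16. It lies on chromosome 3 from 138277585 to 138290698 and had a read in 72.7% of RFP cells. Timd2, a ferritin receptor, followed at 4884 against 9.14 CPM (-8.91), and Havcr1, of the same receptor family, at 648 against 1.87 CPM (-7.82). Pramel7 (-8.24) and Pramel6 (-7.85), of a family expressed in the early embryo, and Dppa1 (-7.80) were in this set. So were Enpep, a membrane aminopeptidase (-8.08), Elf3, an epithelial transcription factor (-7.51), Tspan8, a tetraspanin (-7.58), Fam213a (-8.24), BC053393 (-7.47) and Smpdl3a (-7.34). Each was at 10 CPM or more in at least 31 of 40 GFP cells and in at most 11 of 55 RFP cells.

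Among the 12 with the highest ratio, Enpp2, the enzyme that makes lysophosphatidic acid, was at 860 CPM in RFP cells (857 to 864) and 0.344 CPM in GFP cells (0.272 to 0.430), a log2 ratio of 9.32. It lies on chromosome 15 from 54838901 to 54952789. Tdgf1 (8.71) and Fgf4 (6.82) were in this set with Ldhb, a lactate dehydrogenase subunit (7.93), and Pfkp, a phosphofructokinase (7.39). Gstt2, a glutathione transferase, was at 377 CPM in RFP cells (8.33), Pla2g1b, a phospholipase, at 581 CPM (7.81), and Spp1, a secreted matrix protein, at 3792 CPM (6.70). Sept1 (6.95), Trh (6.91), Enox1 (6.87) and Igfbp2 (6.71) completed it. Each was at 10 CPM or more in at least 24 RFP cells and in at most 8 GFP cells. Across all measured genes, which are not independent replicates, these ratios had a Spearman correlation of 0.839 with the log2 fold changes in the authors' deposited table.

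Genes of the formative state, which follows naive pluripotency as the embryo implants, were higher in RFP cells in 11 of 12 cases by at least 1, with a median of 3.29 (percentile 100). Otx2, a transcription factor of that state, was at 107 CPM against 1.06 CPM in GFP cells, and the de novo DNA methyltransferases Dnmt3a and Dnmt3b at 399 and 432 against 34 and 88.8 CPM. Naive pluripotency genes went both ways, 4 at least 1 higher and 6 at least 1 lower, at a median of -0.18 (percentile 23.4). Nr0b1 (5.49), Klf2 (3.45) and Esrrb (2.91) were higher in RFP cells, while Dppa3 (-4.84), Tfcp2l1 (-3.82) and Klf4 (-3.16) were lower. Core pluripotency genes had a median of 1.59 (percentile 99.8), with Sox2 at 48.7 against 15.5 CPM and Pou5f1, whose count has the same limit from pseudogenes as that of Nanog, at 49.6 against 15 CPM. Only 4 of 13 genes of the totipotent-like state were measured, at a median of 0.52 (percentile 96.1). With each cell weighing the same on the log scale the medians were 1.93 for formative, -0.99 for naive and 0.11 for totipotent-like genes.

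The DNA methylation genes had a median of 1.58 (percentile 100) and its members went both ways. Uhrf1 and Dnmt1, which maintain methylation at replication, were higher in RFP cells (2.93 and 1.80), as was Tet1, a demethylating oxidase (3.10), and Zfp57, which protects imprints (3.72). Dppa3, which blocks maintenance, was at 4750 CPM in GFP cells and 165 CPM in RFP cells, and Tet2 at 163 and 9.68 CPM.

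Most glycolysis genes were higher in RFP cells, 11 of 15 by at least 1, and 2 were lower by at least 1, with a median of 2.37 (percentile 100). Ldha, which makes lactate, was at 1721 against 28.8 CPM, Eno1 at 3285 against 222 CPM and Pkm at 1864 against 144.5 CPM, while the glucose transporter Slc2a3 was lower (-2.46). Nuclear genes of respiration had a median of -0.05 (percentile 20.4) and mitochondrially encoded genes of -0.09 (percentile 26.7), which is the value of mt-Nd4l, with 64 reads in each group. This gene and mt-Nd3, mt-Atp8, mt-Co2 and mt-Co3 were nearly uncounted, at 5.30 CPM or less in GFP cells beside 8842 CPM for mt-Co1. S phase genes had a median of 1.14 (percentile 99.9), led by Mcm3 of the replicative helicase (2.05), and mitosis genes of 0.18 (percentile 54.4). Myc and nucleolar genes stood at 1.16 (percentile 99.9), with Npm1 at 4361 against 1403 CPM, and 91 ribosomal protein genes at 0.56 (percentile 99.9). With each cell weighing the same on the log scale the medians were -0.71 for respiration, 0.56 for S phase, -0.32 for mitosis, 0.71 for Myc and nucleolar and 0.36 for ribosomal protein genes. That of the mitochondrially encoded genes was 0.45 with the mean of CPM over cells. Over all genes the median log2 ratio was 0.08.

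FGF target genes were higher in RFP cells in 8 of 9 cases by at least 1, with a median of 1.93 (percentile 99.3). Etv5 (194 against 1.89 CPM) and Spry2 (818 against 229 CPM), both induced by FGF signalling, were among them. Nodal pathway genes had a median of 2.19 (percentile 99.8), with Lefty1 at 24.5 CPM in RFP cells and no read in GFP cells. Wnt targets stood at 1.43 (percentile 95.7) and immediate early genes at 1.35 (percentile 97.9). These medians were 0.60 for FGF, 0.46 for Nodal, 0.20 for Wnt and 0.19 for immediate early genes with each cell weighing the same on the log scale. Hippo genes had a median of -0.47 (percentile 16.4), with Amot (-5.01) and Tead4 (-3.73), which act in trophectoderm specification, lower in RFP cells and Nf2 higher (2.41).

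Most adhesion genes were lower in RFP cells, 8 of 13 by at least 1 and none higher by at least 1, at a median of -1.22 (percentile 0.11). Dsp, a desmosome protein, was at 148 CPM in GFP cells and 0.135 CPM in RFP cells, and Cdh1, the epithelial cadherin, at 229 and 65 CPM. Connexins, the family of Gjb2, had a median of -1.86 over 6 genes (percentile 1.32; -0.93 at a pseudocount of 10), with Gjb5 lower (-5.13) and Gjc1 higher (5.58). Gjb2 itself was at 4.30 CPM in RFP cells, with 1 cell at 10 CPM or more, and at 0.00895 CPM, from 2 reads, in GFP cells.

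Imprinted genes had a median of 0.68 (percentile 93.6), with Impact (3.55), Zdbf2 (3.68) and Peg3 (2.94) higher in RFP cells and Plagl1 (-4.05) lower. Genes of p53 and apoptosis stood at 0.72 (percentile 94.9), where Trp53 was higher (4.01) and its target Cdkn1a lower (-1.79), and inhibitors of apoptosis at 0.42 (percentile 64.7). Stress genes had a median of 0.67 (percentile 90.4) and placental genes of 1.77 (percentile 93.9), with Plac1 at 138.5 CPM in GFP cells and 0.0964 CPM in RFP cells. Over placental genes at 10 CPM or more in a group the median was -2.21. Feeder fibroblast markers had a median of 0.09 with no member above 3.45 CPM, and oocyte markers of 0.83 with none above 9.51 CPM. Of the X inactivation genes only Rlim was measured (1.12). With each cell weighing the same on the log scale the medians were 0.19 for imprinted, 0.19 for p53, 0.17 for stress, 0.0057 for placental and 0.071 for oocyte genes, and those of the inhibitors of apoptosis and of Rlim were below 0.

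**Figure D3:**
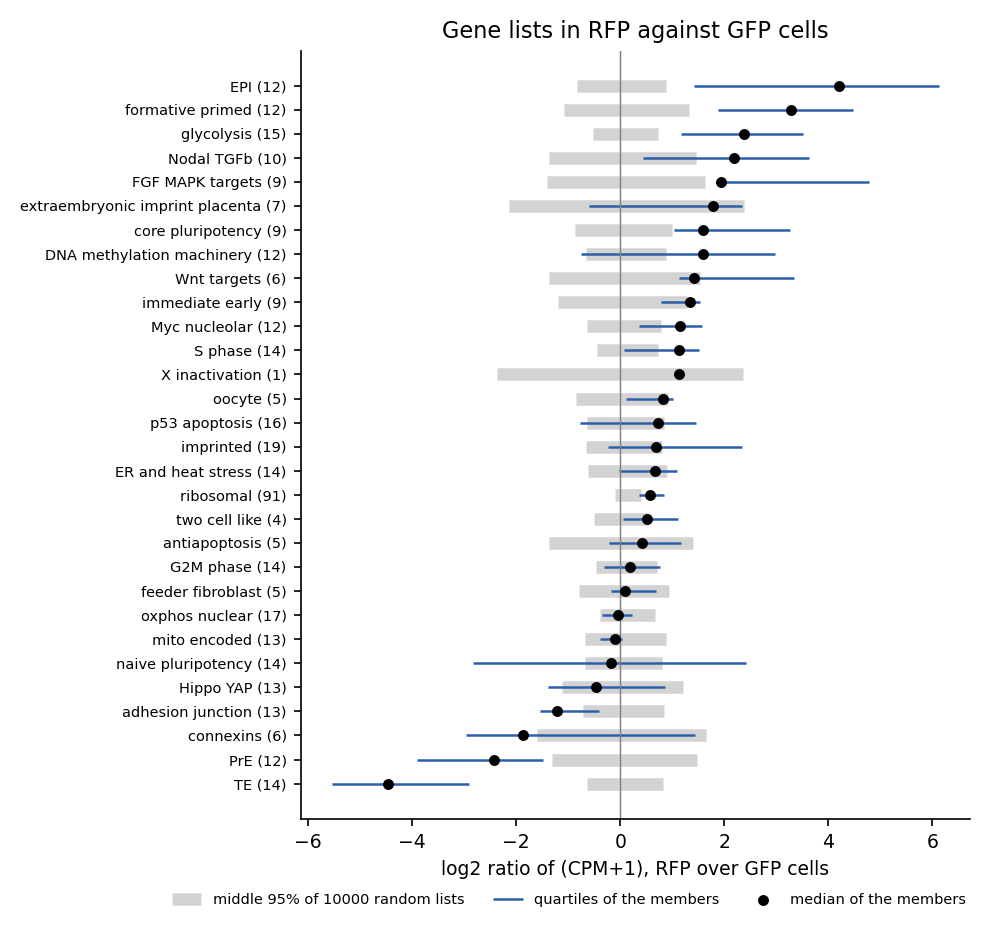
Median log2 ratio of (CPM + 1), RFP over GFP cells, for each fixed gene list (points), with the quartiles of its members (lines) and the middle 95% of 10000 random lists (grey). The number of measured genes is in brackets. The EPI list lies highest at 4.20 and the TE list lowest at -4.47.

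The bisulfite libraries addressed how the methylation of the ESC lines compared with that of fibroblasts. The mean level was 79.1% in MEF, 67.6% in Gjb2-35delG ESCs and 38.5% in Actin-RFP ESCs, over windows with a median of 29, 27 and 28 calls. Windows above 80% made up 60.9%, 27.4% and 1.67% of each library, and windows below 20% made up 2.34%, 4.19% and 18.7%. Against MEF, 71.3% of windows were at least 30 points lower in Actin-RFP ESCs and 0.277% at least 30 points higher, compared with 14.3% and 2.57% in Gjb2-35delG ESCs. In windows with 15 or more CpGs the means were 54.8%, 44.3% and 28.3%. Line, genotype and passage differ together, so none of them can be named as the source of the difference. The ESC libraries also differed from MEF in the share of calls on chromosome X (0.529 and 0.581 of MEF) and Y (1.91 and 2.51). Of the list members below, Hprt, Pgk1, Tex11 and Taf7l lie on chromosome X.

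**Figure D4:**
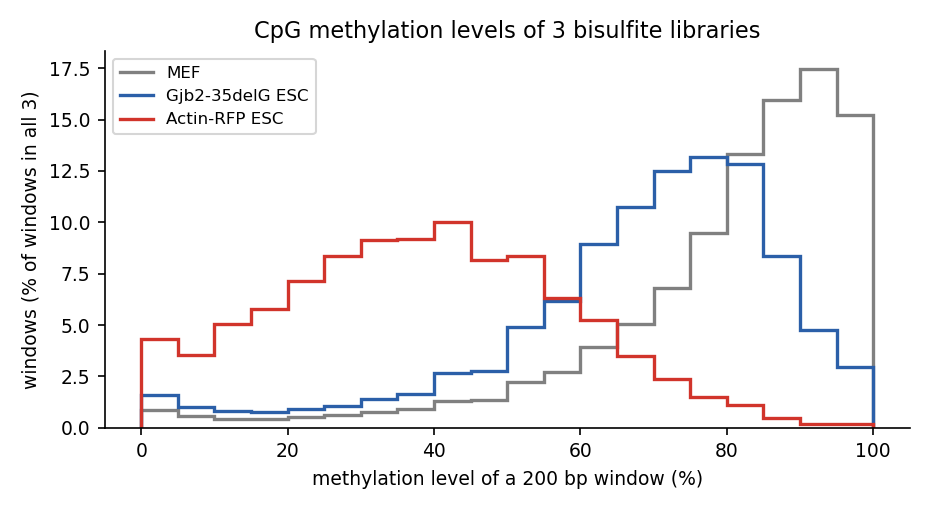
Distribution of the methylation level over windows of 200 bp, as percent of the windows covered in all 3 libraries. MEF peaks above 80%, and Actin-RFP ESCs have 1.67% of windows there.

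Pluripotency genes had gene ends at a median of 64.2% in MEF, 8.66% in Gjb2-35delG ESCs and 3.29% in Actin-RFP ESCs, with all 13 lower than MEF in both ESC lines. The median differences were -40.1 and -50.2 points (both at percentile 0 among random lists matched on the MEF level). At the other gene end the levels were 84.1%, 42% and 19%. Zfp42 stood at 70.7%, 3.53% and 3.14%, and Pou5f1 at 48.8%, 2.75% and 4.52%. Germline genes, which are silenced by methylation in somatic cells, had medians of 86.2%, 64.3% and 35.7%, with all 15 lower in both lines (-24.7 and -51.3 points). Random lists that started at the same MEF level fell less, with medians of -14.7 and -44.1 points, which put the germline genes at percentiles 0.21 and 2.42. With other windows, for which no matched lists were drawn, the germline difference in Gjb2-35delG ESCs was -30.7 points with 500 bp on either side, -17.3 points from 2000 bp upstream to 1000 bp downstream and -14 points at the other gene end. That in Actin-RFP ESCs was -44.3 points with the longer window and at the other gene end. Dazl, a germ cell RNA-binding protein, was at 96.9%, 72.3% and 35.7%.

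Maternally methylated imprinted regions had medians of 56.1% in MEF, 48.7% in Gjb2-35delG ESCs and 24.9% in Actin-RFP ESCs over 14 genes. All 14 were lower than MEF in Actin-RFP ESCs, by a median difference of -30.9 points (matched percentile 68.8), and 11 in Gjb2-35delG ESCs, by -8.41 points (matched percentile 68.2). Snurf was at 43.5%, 43.2% and 27.3%, and Nnat at 58.8%, 47.6% and 13.2%. The end used for Snrpn, from 60449677 to 60451177, was not the place read for Snurf, from 60004699 to 60006199. It is therefore a poor measure of the region read for Snurf. Impact was at 92.8% in MEF, above the list median of 56.1%, and its ends held 28 and 27 CpGs. The end used for it may not cover the imprinted region. The difference in Gjb2-35delG ESCs was -2.60 points with a window of 500 bp on either side. The paternally methylated imprinted genes were H19 (56.9%, 54.4% and 43.1%), Meg3 (49.5%, 57.4% and 30.1%) and Rasgrf1 (3.65%, 10% and 5.03%). They differed from MEF by medians of 6.38 (matched percentile 96.1) and -13.8 points (matched percentile 89.7). The first was -4.84 points at the other gene end. The 6.38 points are the value of Rasgrf1, whose gene end was at 3.65% in MEF and so may not cover its methylated region.

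Fibroblast genes had medians of 32.9%, 52.5% and 29.8%, with differences from MEF of 14.4 and -0.409 points (both at matched percentile 100). At the other gene end they were -14.2 and -39.1 points. The second was 0.190 points with a window of 500 bp on either side and -9.34 points from 2000 bp upstream to 1000 bp downstream. Col1a1, a fibrillar collagen, was at 4.91% in MEF, 69.4% in Gjb2-35delG ESCs and 31.2% in Actin-RFP ESCs. Trophectoderm genes had medians of 49.4%, 18.7% and 11.2% (differences -13.4 and -29.0 points, matched percentiles 7.52 and 34.4). The first difference was -3.38 points at the other gene end and -18.9 as a list mean, and the ESC levels were 38.6% and 33.2% over members with at least 2 times the CpGs at the richer end. Elf5, a methylation-gated trophoblast factor, was at 88.5%, 77.5% and 48%. Its ends held 40 and 36 CpGs, so the end used may not be its promoter. Developmental genes were at 6.69%, 17.2% and 11% (3.97 and 0.919 points, matched percentiles 99.99 and 100). The first was 18.2 points at the other gene end, and the second was -0.0441 points with the shorter window and -1.6 as a list mean. Housekeeping genes were at 22.2%, 10.4% and 4.81% (-9.58 and -15.2 points, matched percentiles 7.31 and 24.7), and their differences were -18.7 and -36.8 points at the other gene end.

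**Figure D5:**
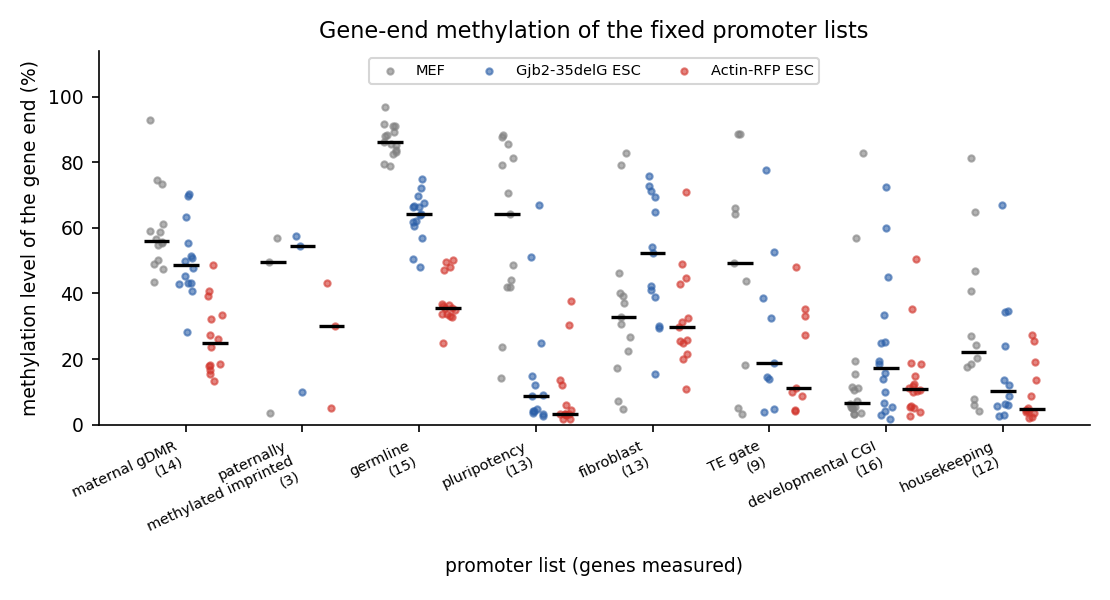
Methylation level of the gene end of each member of 8 fixed lists (points, in percent) in 3 libraries, with list medians as bars and the number of genes in brackets. The pluripotency list falls from 64.2% in MEF to 8.66% and 3.29% in the ESC lines, and from 84.1% to 42% and 19% at the other gene end, which is not drawn.

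The gene ends furthest below MEF were at 86.8% or more in MEF. Tefm, a mitochondrial transcription elongation factor, was at 92.3% in MEF (89.0% to 94.7%, 339 calls), 1.92% in Gjb2-35delG ESCs and 2.5% in Actin-RFP ESCs. Jade1, of a histone acetyltransferase complex, was at 96.1%, 11.4% and 3.0%, and Dppa2, a pluripotency-associated factor, at 88.2%, 9.10% and 1.63%. Trip12, Usp7, Ash2l, Triml1, Mtif2, Ssc4d, Zfp977, Zdbf2 and the predicted genes Gm10461, Gm38457, Gm12569 and 4930548H24Rik were the others, and Ssc4d was still at 53.2% in Gjb2-35delG ESCs. Zdbf2, an imprinted gene, was at 87.2%, 3.76% and 12.7%. Tefm held 46 and 36 CpGs at its ends, Dppa2 34 and 31, Ssc4d 35 and 31 and Ash2l 53 and 42, against 67 and 10 in Jade1. Where the counts are close, the end used may not be the promoter.

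In the other direction, Tlx1, a homeobox gene, was at 8.04%, 79.4% and 40.8%, Fezf1 at 11.3%, 66.0% and 36.7%, and Ferd3l at 6.51%, 64.2% and 36.8%, all developmental transcription factors. Ddr2, a collagen receptor, was at 17.1%, 79.4% and 52.8%. Col3a1, Lum, Tmem176a, Uba7, Fbxo2, Dmbx1, Mamdc2 and Eif2s3y made up the rest with Col1a1. Eif2s3y lies on chromosome Y and had only 30 calls in MEF. At the other end of the gene the sign differed for at least 1 of the named differences of Col1a1 (-7.50 points), Col3a1, Ddr2, Lum, Tmem176a, Uba7, Fbxo2, Dmbx1 and Mamdc2. Between the ESC lines, Vmn1r72, Tbx22, Gm8279, Gm10634, Olfr1047 and 9930111J21Rik2 were lowest in Actin-RFP ESCs, with Tbx22 at 76.3% and 12.3%, and Eps8l1, Aim2, Gm1966, Klhl7, Scaf4 and Slc39a1 highest, with Eps8l1 at 35.1% and 63.6%. These last 6 were lower in Actin-RFP ESCs at the other end of the gene. Among the lowest, Tbx22 had only 23 calls in Actin-RFP ESCs (4.15% to 31.2%), Gm8279 24, Vmn1r72 25 and 9930111J21Rik2 29. Olfr1047 had 129 calls there and Gm10634 203. The gene end of Gjb2 was at 22.9%, 33.1% and 16.1%.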

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

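The tests of explanations in this part were all chosen after the results they bear on were seen.

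Genes that were high in GFP cells left a trace in RFP cells. Of 343 genes at 500 CPM or more in GFP cells, 10 were below 1% of that level in RFP cells, among them Adh1, Timd2 and Dppa1, and none was without a read. RFP cells in TE-like clusters held a median of 18.1% of these reads, which argues against a few such cells as the whole source. A median of 60% of RFP cells had a read of such a gene, above the upper limit of 20.9% for random genes of the same level, which argues against ordinary low expression and is consistent with reads from the libraries of other cells. The mirrored set of 6 genes gave 61.3% of GFP cells against 28.8%, so part of these traces, at a median of 0.340% of the level in GFP cells, may not be expression, and no limit for them was measured.

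Minor allele reads were found in every amplicon. The 35delG share of the 25 amplicons below 1% differed by 32.5 times between the highest and the lowest, which argues against one fixed rate of miscalled reads. The highest were testis and tail of number 2 (0.601% and 0.533%) and brain and heart of number 3 (0.537% and 0.581%). These follow each other in the order of the amplicons. The lowest were all of number 12 (0.0185% to 0.0304%), and numbers 1 to 4 were at 0.225% or more. Whether the spread goes with this order was not tested. The table gives each amplicon a first number, and 3 of the 6 sets so numbered held only amplicons rich in 35delG. WT reads there reached 5.53%, in brain of number 6, which argues against exchange within a set as the whole source. Wild-type cells in the tissues could give WT reads and stay open as untested, as does exchange across sets. WT shares of the 35G amplicons differed by 115 times, from 0.0153% in tail to 1.77% in liver. The other tissues lay closer together, at 0.121% to 0.403%.

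In Actin-RFP ESCs 48.3% of windows were at least 30 points below Gjb2-35delG ESCs and 0.139% above. If methylated calls had been lost at one rate, independently of each other, 0.569 of a full level would remain. Then 45.4 of about 1175260 windows with at least 50 calls in each library would reach 80%, but 9416 did. Calls on the same read are not independent, which raises the number to be expected, and by how much was not measured. MEF DNA in the Gjb2-35delG library would need a share of 71.8%, and 5811 windows high in MEF and at 5% or less in Actin-RFP ESCs would then be at 64.9%, but the median there was 7.68% (quartiles 4.19% to 14.8%). The second result argues against MEF DNA as the whole cause. The first argues only against loss of single calls independently of each other, and leaves open loss that acts on whole reads. Line, passage and genotype were not tested, with 1 library per line, and stay open.

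Reads classed as Other were in no comparison and reached 0.327% in heart of number 4 (1701 of 520921 reads), and what this class holds is not given in the sources used here. The paternally methylated imprinted genes differed from MEF by 6.38 points in Gjb2-35delG ESCs and by -13.8 points in Actin-RFP ESCs, without a test. These medians come from different genes: Rasgrf1 was higher than MEF in both lines (6.38 and 1.37 points), H19 lower in both (-2.49 and -13.8 points), and only Meg3 changed direction (7.91 and -19.4 points). At the other gene end the first median was -4.84 points. In MEF the gene end used for Rasgrf1 was at 3.65%, so it may not cover the methylated region. Fibroblast gene ends differed by 14.4 and -0.409 points, also without a test, and by -14.2 and -39.1 points at the other gene end.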

How the results depend on the processing

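The alternatives that left out cells above 10% mitochondrially encoded reads, used the gene end with fewer CpGs or kept members with at least 2 times the CpGs at the richer end were chosen after the data were seen, as was the matching of random promoter lists on the MEF level, which changes no list value. With random lists of any gene ends, as planned, germline genes were at percentile 0 in both ESC lines, and the paternally methylated genes at 98.5 in place of 96.1 in Gjb2-35delG ESCs. No paired analysis was possible because the numbers in the labels name single cells and the results come from no test. Not run were the comparison within EPI-like or TE-like cells, with fewer than 5 cells of one group in each class, the pooling with RFPpos and GFPpos cells, not analysed here, the averaging of all transcription starts, and the leaving out of a testis sample, since amplicons have no sample. Removing the cell filter, or a minimum of 1 call, moved nothing because no cell or window was affected. Of the list medians of the cells, 62 moved by more than 1 SD of random lists and 205 did not, and 5 values changed sign: placenta, mitosis, mitochondrially encoded genes, inhibitors of apoptosis and Rlim; of the promoter values, 47 moved, 7 changed sign and 186 did neither. Of the named genes, 24 values moved and 168 did not, and none changed sign. Of the named gene ends, 73 moved, 19 changed sign and 113 did neither. The cause was not tested for any value below. Depth limits genes near 1 CPM and gene ends with few calls.

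Without Other reads, 35delG shares were 99.8% (brain), 99.9% (heart), 98.2% (liver), 99.6% (testis) and 99.98% (tail), and without classes under 1% of reads 100% in all but liver (98.2%).

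In cells with at least 4000 genes (34 GFP, 35 RFP), medians were 5.30 (EPI), -5.06 (TE), -0.60 (naive), 0.014 (totipotent-like), 0.55 (mitosis) and 0.084 (placenta). With the mean of CPM over cells they were 0.95 (totipotent-like) and 0.45 (mitochondrially encoded). With the mean of log2(CPM + 1) they were 3.22 (EPI), -0.32 (PrE), -3.94 (TE), 0.071 (oocyte), -0.99 (naive), 1.93 (formative), 0.11 (totipotent-like), 0.19 (p53), 0.71 (Myc), -0.71 (respiration), 0.56 (S phase), -0.32 (mitosis), 0.17 (stress), 0.19 (immediate early), 0.60 (FGF), 0.20 (Wnt), 0.46 (Nodal), -1.75 (adhesion), 0.19 (imprinted), 0.0057 (placenta) and 0.36 (ribosomal). With members at 10 CPM or more in a group they were 4.95 (EPI), -4.10 (PrE), -5.30 (TE), -1.15 (naive), 4.81 (Wnt), 1.40 (Nodal), 1.10 (imprinted) and -2.21 (placenta). At a pseudocount of 0.1 they were -5.15 (PrE), -5.46 (TE), 0.72 (feeder), 1.94 (oocyte), 4.63 (formative), 2.0 (totipotent-like), 4.30 (FGF), 4.13 (Wnt), 3.72 (Nodal) and 1.52 (imprinted). At 10 they were 2.78 (EPI), -0.58 (PrE), -2.47 (TE), 0.13 (oocyte), 1.6 (formative), 0.069 (totipotent-like), 0.31 (p53), 0.84 (FGF), 0.23 (Wnt), 0.67 (Nodal), -0.93 (connexins), 0.15 (imprinted) and 0.54 (placenta). Without cells above 10% mitochondrially encoded reads they were 5.19 (EPI) and 0.0095 (totipotent-like).

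EPI-like GFP cells were 0% with 4000 variable genes, at least 4000 genes, marker z-scores without clusters, or without cells above 10% mitochondrially encoded reads. TE-like GFP cells were then 100% except by z-score, which put 10% of GFP and 10.9% of RFP cells in PrE-like. Mean log2 PrE levels of RFP cells were at most 1.39, so these RFP calls rest on low levels. Without cells above 10% mitochondrially encoded reads, RFP cells were 100% EPI-like and 0% TE-like.

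Mean methylation (MEF, Gjb2-35delG ESC, Actin-RFP ESC) was 78.9%, 67.6% and 38.4% over own windows, 79.1%, 67.6% and 38.5% on autosomes, 79.3%, 67.6% and 38.8% at 10 calls, 78.2%, 66.2% and 38.8% weighted by calls and 84.4%, 71.7% and 38.5% as medians.

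Promoter lists are given as points against MEF for Gjb2-35delG (G) and Actin-RFP (A) ESCs. With 500 bp on either side they were -2.60 (gDMR, G), -30.7 (germline, G), -35.4 (pluripotency, G), 0.190 (fibroblast, A, level 22.2%) and -0.0441 (developmental, A). From 2000 bp upstream to 1000 bp downstream they were -37.9 (gDMR, A), -17.3 and -44.3 (germline, G and A), -45.8 (pluripotency, G), 10.1 and -9.34 (fibroblast), -15.9 and -24.4 (housekeeping). As list means they were -18.9 (trophectoderm, G; level in A 20.3%) and -1.6 (developmental, A), and over own windows 3.49 (fibroblast, A). With 2 times the CpGs they were -4.78 (gDMR, G), -46.1 (pluripotency, G; MEF level 48.8%), 3.49 (fibroblast, A) and -5.45 (housekeeping, G), with trophectoderm levels of 38.6% (G) and 33.2% (A). At the end with fewer CpGs they were -46.6 (gDMR, A), -4.84 (paternal, G), -14 and -44.3 (germline), -14.2 and -39.1 (fibroblast), -3.38 (trophectoderm, G), 18.2 (developmental, G), -18.7 and -36.8 (housekeeping). Levels there (MEF, G, A) were 81.2%, 71.7% and 33.1% (gDMR), 85.2%, 80.2% and 52.8% (paternal), 84.1%, 42% and 19% (pluripotency), 27.7%, 45.5% and 30.8% (developmental), 81.2%, 56.1% and 35.8% (housekeeping), 79.4% (fibroblast, MEF), 61.6% and 38% (trophectoderm, G and A) and 27.8% (germline, A).

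Among named gene ends, Col3a1 (A against MEF) was at -13.9 from 2000 bp upstream to 1000 bp downstream and Klhl7 (A against G) at -1.99 over own windows. At the end with fewer CpGs, values against MEF were -58.3 (Col3a1, A), -17.7 and -44.1 (Ddr2, G and A), -23.2 (Dmbx1, A), -10.9 (Fbxo2, G), -6.33 and -34.9 (Tmem176a, G and A), -18.3 (Uba7, A), -52.4 (Lum, A), -7.50 (Col1a1, A) and -6.23 (Mamdc2, G). Values of A against G there were -51.4 (Aim2), -3.15 (Slc39a1), -23.5 (Klhl7), -26.7 (Eps8l1), -31.3 (Gm1966) and -19.4 (Scaf4).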

Other observations

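The observations in this part, and the choice of genes in them, were all made after the data were seen, and no explanation was tested for them.

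The genes lowest in RFP cells included neighbours on chromosome 11. Between 46524251 and 46779578 (GRCm38, 255 kb), all 5 measured genes were at least 5 lower on the log2 scale in RFP cells: Gm12169 (180.7 against 1.84 CPM), BC053393 (1065 against 5.02 CPM), Dppa1 (1975 against 7.85 CPM), Timd2 (4884 against 9.14 CPM) and Havcr1 (648 against 1.87 CPM). Of the next measured genes on either side, Med7, a Mediator subunit, was at 251.5 and 174 CPM. Timd4 was at 0.0403 and 0.0321 CPM, too low in both groups to show a difference, so the end of the run on that side is not known. Pramel6 and Pramel7 also lie beside each other, on chromosome 2.

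A Y-linked gene at 10 CPM or more was found in 25 of 40 GFP cells (62.5%, exact interval 45.8% to 77.3%) and in 35 of 55 RFP cells (63.6%, 49.6% to 76.2%). A further 9 GFP and 11 RFP cells had a top Y-linked gene above 0 and below 2 CPM, and 6 and 7 had no Y-linked read. Such shares also depend on how well these genes are detected in a single cell, so they are not read as shares of male cells. In the bisulfite libraries, the share of calls on chromosome X was 0.529 of that in MEF for Gjb2-35delG ESCs and 0.581 for Actin-RFP ESCs, and on chromosome Y 1.91 and 2.51. Windows below 5 calls per CpG are not in these totals.

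Thinned to 500000 reads, GFP cells had a median of 4657 detected genes and RFP cells 4039, against 5209 and 4527 without thinning. Mitochondrially encoded reads made up a median of 3.12% in GFP and 2.65% in RFP cells, with a highest value of 62.0% in an RFP cell.

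The numbered amplicons have no label for animal or genotype. Median 35delG shares over 5 tissues were 0.269%, 0.317%, 0.310% and 0.253% for numbers 1 to 4 and 0.0232% for number 12. For numbers 5 to 11 they were 99.5%, 99.5%, 99.7%, 98.8%, 99.3%, 99.7% and 99.2%.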
